A study of Homo sapiens with 2 samples.

How the data were processed

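The libraries were made with 10x Genomics Chromium 3' v3 chemistry from cells grown for 14 days in mouse bladders, per the labels, with 10000 cells added to each channel. The deposited matrices hold raw UMI counts per gene and barcode, written by Cell Ranger 3.1.0 against GRCh38 per the file headers and the submitters' processing notes. The notes do not say whether a mouse genome was part of the reference, and all 33538 genes listed are human. Reads from mouse cells may therefore have been counted as human genes or lost. The strand rule and other counting settings are not given in the sources used here. Each deposited matrix lists 6794880 barcodes, so the counts had not been restricted to cells.

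Barcodes were called as cells when their UMI count was at least the 99th percentile of the top 3000 barcodes of their library divided by 10, with at least 200 genes and at most 20% mitochondrial UMIs. The cutoffs were 13424 UMIs in the control library, passed by 4464 barcodes, and 15676.8 in the knockdown library, passed by 2638. Scrublet marked 0 control and 5 knockdown barcodes as doublets, 0.190% of the latter. A caller that marks so few has not worked, so doublets were in effect not removed. After all filters 4462 and 2631 cells remained.

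Cells of both libraries were clustered together with scanpy 1.11.5 and igraph 0.11.9 on log-normalised counts with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5, without batch correction since library and group coincide. Clusters were to be named from 11 marker lists. No cluster had a UMUC3 marker among its top 10 genes, which were ranked by fold over all other called cells. Genes at similar levels in most cells cannot lead such a ranking. In every cluster 10 or 11 of the 12 UMUC3 markers reached 10 CPM. Cluster 5 had the neutrophil marker G0S2 there, and cluster 9 the T and NK cell marker CCL5. Cluster 10 had the fibroblast markers COL1A1, COL1A2 and COL3A1. The named class was therefore not used for comparison. The fallback fixed in advance was used instead: counts were summed over all called cells of each library. The setting of all called cells, also fixed in advance, is thus identical to the values given. Cell phases were scored from the S phase and the G2 and M phase lists after thinning each cell to 21971 UMIs.

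Summed counts were divided by library totals. Ratios carry exact conditional binomial 95% intervals, single values exact Poisson intervals and shares Clopper-Pearson intervals. All cover counting error only, as do limits of 3 counts for values of 0. A gene was measured with at least 10 CPM in either library, which 7873 genes were, with a median log2 ratio of -0.07. A list member was called higher or lower at a ratio of at least 1.5 with an interval excluding 1, a rule of size and not a test. Each list median was placed among 10000 random lists of equal size matched on mean expression in 20 bins. Gene positions were matched by identifier to the GENCODE release 29 annotation of GRCh38 for 33456 genes.

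Cell calling, the 27 gene lists, the marker lists, the size rule, the naming rule and the first set of alternative settings were fixed before the data were examined. The lists were the ER glucosidase and calnexin cycle, oligosaccharyltransferase, ER-associated degradation, ATF6 and XBP1 target ER chaperones, ATF4 and CHOP integrated stress response, Golgi N-glycan processing, lysosome, mesenchymal, epithelial and urothelial, extracellular matrix, integrins and adhesion receptors, growth factor receptors and ligands, S phase, G2 and M phase, type I interferon response, MHC class I presentation, NF-kB targets and chemokines, hypoxia and glycolysis, mitochondrially encoded, nuclear oxidative phosphorylation, ribosomal proteins, MYC targets, p53 targets, cholesterol synthesis, NRF2, immediate early genes and cytosolic heat shock. Of their genes and the markers together, 643 of 650 symbols were found. Some genes stand in more than 1 list, such as SPARC, AXL, LDHA and CCL5.

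The naming rule took, per direction, the 12 genes with the largest ratio (0.5 counts added to each sum) among those with at least 50 CPM in the higher library, leaving out mitochondrially encoded genes, clone-based names and pseudogene-like copies of ribosomal proteins. GANAB and PRKCSH were always named. Values of some single genes that the rule took, and a test that needed them, are not reported here, while list counts and medians include all measured members. Up to 4 members were named per list, by ratio in the direction of its median and by mean expression, and 5 leading genes per cluster. Other members, named only to spell out small counts, were chosen after their values were seen, and so were SOX4, CDH2 and the genes of the closing section.

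The calling and interval code was tested on simulated counts with 200 changed genes. Over all called cells (7452 genes) all 50 genes at each fold of 0.25, 0.5, 2 and 4 were called in the right direction and intervals covered 95.7% of true values. In cluster 1 (7446 genes) all were called and 95.5% covered, and in cluster 3 (7400 genes) 49 of 50 at a fold of 0.5 and all at the others, with 95.8% covered. Counts were drawn from the Poisson model that the intervals assume, so the coverage checks the code and not the spread between cells. A list of 50 unchanged genes lay at percentile 20.57 over all cells, 93.45 in cluster 1 and 96.65 in cluster 3. Alternatives covered cell calling, normalization (edgeR 4.0.16 TMM factors, median-of-ratios factors, totals without mitochondrial and ribosomal genes), cells summed, ambient subtraction, low-count filters, clustering and thinning. Values within clusters 1 and 3, and 4 further choices of cells, were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.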

Results

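Messenger RNA of single cells was counted in 2 libraries of UMUC3, a human bladder carcinoma line, after 14 days of growth in the bladders of nude mice. The first library came from cells labelled as control and the second from cells with a knockdown of GANAB, which encodes the catalytic alpha subunit of glucosidase II, an enzyme of the endoplasmic reticulum (ER) that trims glucose from newly made N-glycans. About 10000 cells were loaded per channel, per the labels. The control library held 239857346 unique molecular identifiers (UMIs), of which 215284902 lay in 4462 called cells with a median of 43600.5 UMIs (order-statistic 95% interval 42896 to 44508) and 5875.5 genes. The knockdown library held 155064055 UMIs, of which 131712586 lay in 2631 called cells with a median of 41293 UMIs (40115 to 42546) and 5657 genes. With 1 library per group no difference below has a replicate check, no test across samples was possible, and every interval covers counting error only. The words higher and lower therefore compare these 2 libraries, with expression given as CPM, the UMIs of a gene summed over all called cells and scaled to a common library total.

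GANAB (ENSG00000089597; GRCh38 chromosome 11, 62624826 to 62646726) was counted at 127 CPM in the control library (27244 UMIs; 95% Poisson interval 125 to 128) and at 42.3 in the knockdown library (5578 UMIs; 41.2 to 43.5). The log2 ratio of knockdown over control was -1.58 (exact conditional binomial 95% interval -1.62 to -1.54), a 2.99-fold lower level in the library labelled as the knockdown. PRKCSH (ENSG00000130175; chromosome 19, 11435288 to 11450968), the beta subunit of the same enzyme, stood at 80.4 in control and 46.3 in knockdown cells, 1.74-fold lower. Clustering of all cells gave 10 clusters, none of which was compared as a named cell type under the rule fixed in advance. Cluster 1 held 1638 knockdown and 154 control cells, and cluster 3, with TOP2A among its leading genes, held 838 knockdown and 149 control cells. Control cells of clusters 1 and 3 kept GANAB at 124 and 139 CPM, whereas the knockdown cells beside them had 39.0 and 45.0. The ratio within cluster 1 was thus -1.66 (interval -1.78 to -1.54) and within cluster 3 -1.63 (-1.73 to -1.54). Outside clusters 1, 3 and 9 lay 51 knockdown cells. In cluster 2, 14 had GANAB at 91.9 CPM (69.2 to 120) beside 119 in control cells. In cluster 4, 3 had 145 (82.8 to 235) beside 107, and in cluster 8, 6 had 78.3 (41.7 to 134) beside 101. Knockdown cells were lower in clusters 5 (48.0 and 134), 6 (68.7 and 140) and 10 (26.2 and 117), and cluster 7 held 1. A lower GANAB was thus not clear in every cluster, and the cause was not tested.

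**Figure D1:**
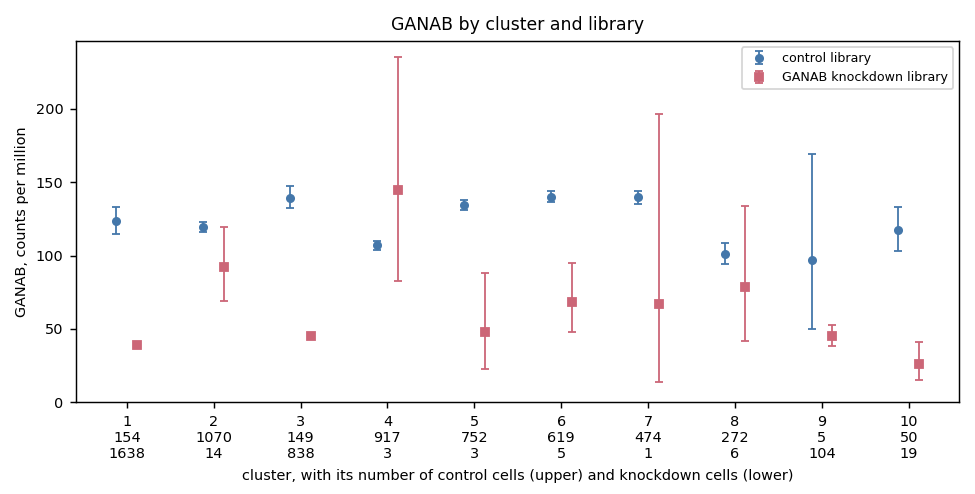
GANAB in CPM (linear axis from 0) by cluster and library, with exact Poisson 95% intervals as bars and the numbers of control and knockdown cells under each cluster number. In clusters 1 and 3, which hold 2476 of the 2631 knockdown cells, control cells lie at 124 and 139 and knockdown cells at 39.0 and 45.0. The 14 knockdown cells of cluster 2 and the 3 of cluster 4 lie at 91.9 and 145, with wide intervals.

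The 303 control cells of clusters 1 and 3 differed from the other control cells in more than their grouping, which bears on every contrast between the whole libraries. SPANXB1, a cancer-testis gene, was at 189 CPM in these cells, 0.614 in the other control cells and 305 in the knockdown cells of the same clusters. FAM133A (153, 14.7 and 141) and the long noncoding RNA TMEM132D-AS1 (121, 1.03 and 132) parted the control cells in the same way, and MAN1A1, a Golgi mannosidase, was low where these were high (2.34, 82.5 and 0.374). These genes took part in the clustering. Over 4713 autosomal genes that did not, windowed log2 ratios against separate sets of the other control cells correlated at 0.912 between the 303 control cells and the knockdown cells across 117 windows, which are not independent replicates. In the window of chromosome 11 with gene starts from 12674591 to 45909669, the ratio was -0.78 in knockdown cells and -0.67 in these control cells. In that of chromosome 9 with gene starts from 89318506 to 113255835, it was 0.48 and 0.50. Values within clusters 1 and 3 are therefore given for many of the genes and lists below, and genes given for the whole libraries alone may also part there. The control cells of these clusters were grouped by likeness to knockdown cells, which can by itself shrink ratios within the clusters. Such ratios are therefore no corrected measure of the difference.

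**Figure D2:**
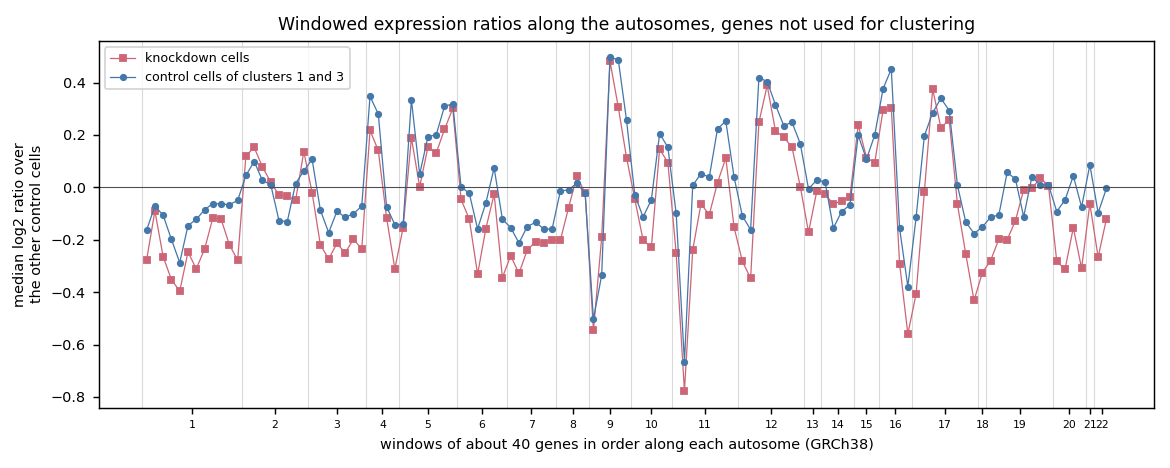
Median log2 ratio over the other control cells in windows of about 40 genes ordered along each autosome (GRCh38), for knockdown cells (squares) and for the control cells of clusters 1 and 3 (circles). Both lines dip together on chromosome 11 (-0.78 and -0.67) and peak together on chromosome 9 (0.48 and 0.50).

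The first question the design poses is how the machinery that folds and trims glycoproteins in the ER stood beside the lowered GANAB. Of the 14 measured members of the glucosidase and calnexin cycle list, 4 were lower (GANAB, PRKCSH, CALR and LMAN1) and none higher by the size rule, a ratio of at least 1.5 with an interval excluding 1. CALR, a lectin chaperone that binds monoglucosylated glycans, was at 529 CPM in control and 285 in knockdown cells, while its membrane-bound relative CANX (366 and 354) was not past the rule. The list median was -0.23, at percentile 12 of 10000 random lists matched on expression. Within clusters 1 and 3 the medians were -0.14 and -0.20 with 2 members lower in each, and CALR stood at 302 against 229 and 476 against 347. Chaperones that ATF6 and XBP1 induce in the unfolded protein response had 5 of 18 members lower (HSPA5, MANF, PDIA4, P4HB and SDF2L1) and none higher, with a median of -0.41 at percentile 0.07. HSPA5, the main ER Hsp70, was at 805 in control and 466 in knockdown cells, MANF at 142 and 73.8, and HSP90B1 at 662 and 461, whereas SEC61B of the translocon was at 394 and 547. Within clusters 1 and 3 the medians of this list were -0.14 and -0.15, with 1 and 0 members lower, and HSPA5 stood at 586 against 361 and at 828 against 569.

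Neighbouring secretory lists lay closer to 0. None of the 12 measured oligosaccharyltransferase subunits passed the size rule (median -0.11, percentile 37.0), with RPN1 at 103 and 74.2, RPN2 at 264 and 199 and OST4 at 416 and 586 CPM in control and knockdown cells. ER-associated degradation had 2 of 18 lower, HERPUD1 (148 and 84.9) and the segregase VCP (151 and 95), with a median of -0.09; the log2 ratios of HERPUD1 within clusters 1 and 3 were -0.46 and -0.07. Golgi N-glycan processing had 2 of 11 lower, MAN1A1 and MAN2A1, and 1 higher, MGAT5, around a median of 0.01. MAN1A1 was the gene with the lowest ratio among those named, at 77.0 in control and 1.09 in knockdown cells; within clusters 1 and 3 it stood at 2.68 against 0.469 and 2.14 against 0.269. The integrated stress response driven by ATF4 and CHOP had 4 of 17 members higher and none lower (median 0.19, percentile 99.4), which were ATF3, PSAT1, NUPR1 (1.14 and 23.2) and PHGDH (20 and 44.3), a serine synthesis enzyme. The list median was 0.01 within cluster 1 and -0.15 within cluster 3. PHGDH was not higher within clusters 1 and 3, at 35.8 against 34.1 and 77.9 against 57.6, and NUPR1 was higher within cluster 1 alone (14.3 against 36.9; cluster 3, 6.73 against 5.74). Lysosomal genes had 1 of 18 higher and 1 lower, CTSA, with a median of 0.11; within the clusters the medians were -0.10 and -0.13. The highly expressed PSAP was at 1125 in control and 767 in knockdown cells.

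Sterol synthesis was lower throughout its pathway. All 20 measured members of the cholesterol synthesis list were lower in the knockdown library, with a median of -1.12 at percentile 0.00 of the random lists. HMGCS1, which makes the HMG-CoA that feeds the mevalonate pathway, was at 329 CPM in control and 90.2 in knockdown cells, MSMO1 at 192 and 52.1, and MVD at 33.1 and 8.35. Part of this gap also separated the control cells of clusters 1 and 3 from other control cells. Within cluster 1 the median was -0.54 with 9 members lower, and within cluster 3 it was -0.75 with 12 lower. There HMGCS1 stood at 147 against 55.0 and at 250 against 127, and MSMO1 at 79.7 against 32.2 and 150 against 72.9.

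Among the other genes with the lowest ratios, MME, the membrane peptidase neprilysin, was at 152 CPM in control and 8.99 in knockdown cells, 17.0-fold lower, and within clusters 1 and 3 at 8.94 against 1.45 and 46.5 against 14.9. VGF, a neurosecretory protein, was at 263 and 27.1, C15orf48 at 59.5 and 6.37, and the bradykinin receptor BDKRB1 at 51.5 and 8.21. These last 3 did not pass the size rule as lower within clusters 1 and 3, where VGF stood at 12.9 against 13 and at 39.6 against 41.5, C15orf48 at 2.86 against 2.77 and 4.49 against 8.88, and BDKRB1 at 2.5 against 6.32 and 2.03 against 9.84. CD82, a tetraspanin, was at 111 and 21.3, but at 30.4 against 17.3 and 25.3 against 24.1 within the clusters. DSE, an epimerase of dermatan sulfate synthesis, was at 55.8 and 13.3, GMDS, which starts GDP-fucose synthesis, at 53.2 and 15.1, and TMEM158 at 274 and 86.5. Within clusters 1 and 3 the gaps were smaller, with DSE at 20.9 against 12.8 and 21.9 against 12.9, GMDS at 24.8 against 13.9 and 20.7 against 15.5, and TMEM158 at 69.0 against 52.7 and 219 against 120.

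**Figure D3:**
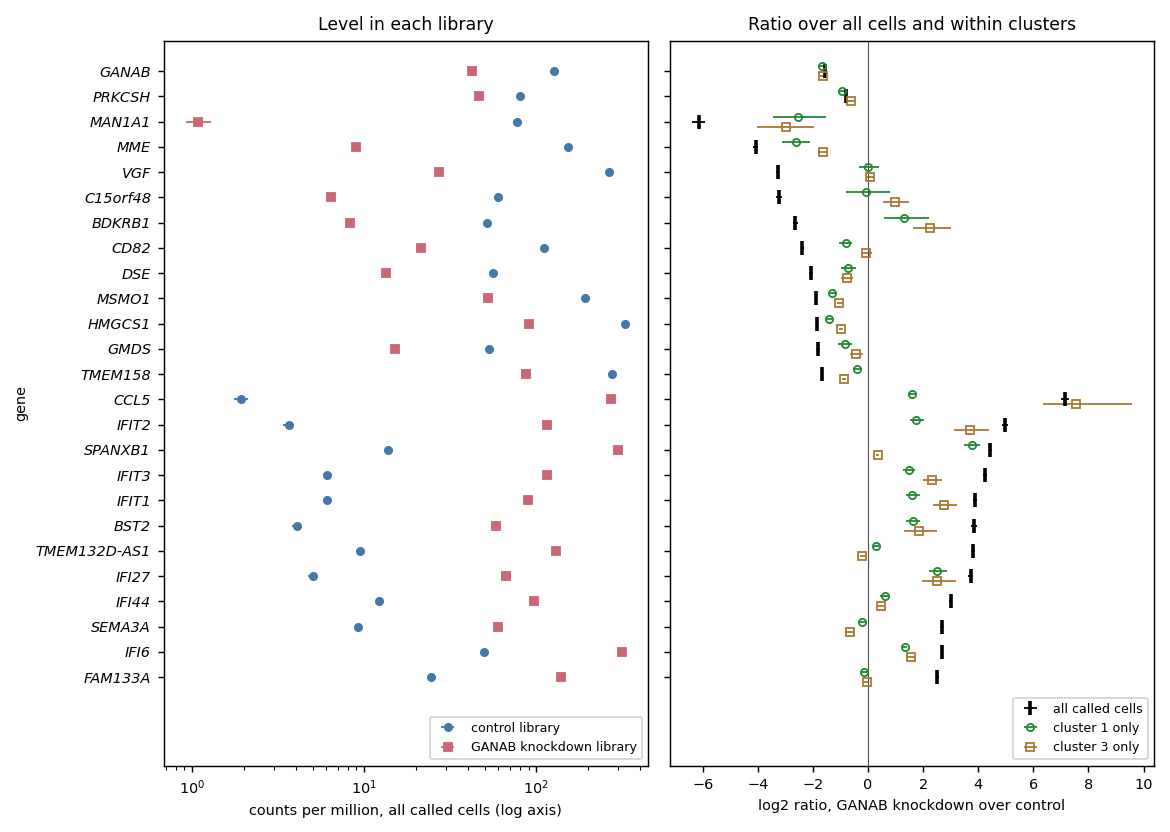
CPM in the control (circles) and knockdown (squares) libraries on a log axis, left, and log2 ratios over all called cells and within clusters 1 and 3, right, for 25 genes named by rule; bars are exact 95% counting intervals. GANAB keeps its ratio within the clusters (-1.66 and -1.63 beside -1.58), while VGF, SEMA3A and FAM133A lie near 0 or on the other side.

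Interferon-stimulated genes made up most of the genes with the highest ratios. Of 24 measured members of the type I interferon list, 22 were higher and none lower in the knockdown library, with a median of 1.96 at percentile 100 of the random lists. IFIT2 was at 3.64 CPM in control and 115 in knockdown cells, 31.6-fold higher, and IFIT3 (6.10 and 115) and IFIT1 (6.05 and 89.0) were close to it. IFI6 was at 49.4 and 314, IFI27 at 5.01 and 66.3, IFI44 at 12.2 and 97.4, ISG15 at 173 and 699, and BST2, which tethers budding virions, at 4.05 and 57.9. The chemokine CCL5 had the highest ratio of all named genes, at 1.92 and 272, 141-fold higher, and stood at 49.7 against 151 within cluster 1 and 0.427 against 89.3 within cluster 3. The 104 knockdown cells of cluster 9, led by interferon genes, held 44.6% of the IFIT1, IFIT2 and IFIT3 UMIs of their library; without that cluster the list median was 1.72, and CCL5 was at 120 in the other knockdown cells. Within cluster 1 the median was 0.54 with 11 members higher and 2 lower, and within cluster 3 it was 0.84 with 14 higher. IFI6 stood there at 174 against 439 and at 36.1 against 106, and IFIT2 at 23.8 against 80.4 and 2.46 against 32.2, whereas IFITM3 (499 and 835 in the whole libraries) stood at 1509 against 926 and 633 against 628. IFI44 was already at 61.8 in the control cells of clusters 1 and 3, beside 8.53 in the other control cells. Within the clusters it stood at 60.8 against 92.4 and 62.5 against 86.3.

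Medians of related immune lists were smaller. Class I antigen presentation had 3 of 14 members higher and none lower (B2M, HLA-B and HLA-F; median 0.32, percentile 99.9), with B2M, the shared light chain, at 959 CPM in control and 2348 in knockdown cells. Within clusters 1 and 3 no member passed the size rule in either direction, the medians were -0.14 and -0.07, and B2M stood at 2376 against 3024 and 1081 against 1352. The list of NF-kB targets and chemokines had 5 of 14 higher and 1 lower, with a median of 0.33 at percentile 99.97, and medians of 0.04 and 0.66 within clusters 1 and 3. Over all cells it was 1.33 at a minimum of 50 CPM, 0.18 with cells weighted equally and 0.12 in G1 cells. CCL2 was the lower member. CXCL2, a neutrophil chemoattractant, was at 38.4 and 133, within the clusters at 66.1 against 123 and 83.6 against 148, and NFKBIA was at 438 and 566. HLA genes, CXCL1 to CXCL3, the IFIT and IFITM families and SPANXB1 have related copies. Where copies are near-identical, reads may be split among them or lost, and single-gene values are uncertain there.

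The remaining genes with high ratios were also high in the control cells of clusters 1 and 3. Those cells were grouped there by likeness to knockdown cells, so small ratios of these genes within the clusters were partly set in advance. SPANXB1 was at 13.7 CPM in the control and 298 in the knockdown library, TMEM132D-AS1 at 9.38 and 131, the axon guidance factor SEMA3A at 9.22 and 59.7, and FAM133A at 24.4 and 139. SEMA3A within clusters 1 and 3 stood at 99.9 against 85.8 and 47.2 against 30.2, FAM133A at 146 against 132 and 158 against 152, and TMEM132D-AS1 at 130 against 160 and 116 against 100. SPANXB1 was higher in the knockdown cells within cluster 1 (17.9 against 245) and differed less within cluster 3 (292 against 371). TMEM132D-AS1 overlaps another gene in antisense, and the strand rule of the counting is not given in the sources used here.

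The S phase list was lower in the knockdown library by its median. Of 38 measured S phase genes, 17 were lower and none higher, with a median of -0.52 at percentile 0.00. MCM7, a subunit of the replicative helicase, was at 151 CPM in control and 67.0 in knockdown cells, the sliding clamp PCNA at 263 and 143, and CDC45 at 19.9 and 9.45. The G2 and M phase list had 9 of 54 lower and 1 higher (median -0.41, percentile 0.00), with KIF2C at 27.2 and 14.0, CDC20 at 122 and 70.5 and UBE2C at 635 and 446. When each cell counted equally, 28 members were lower. With every cell thinned to 21971 UMIs, 50.9% of 4026 control cells (Clopper-Pearson 95% interval 49.4 to 52.5) and 29.3% of 2357 knockdown cells (27.4 to 31.2) scored as S or G2M, with 436 and 274 shallower cells left out. Without thinning the shares were 50.7% and 28.8%. Scores of 392 control and 149 knockdown cells lay within 0.02 of the boundary, and free RNA differs between the libraries, so phase calls alone do not measure cycling. Among cells of clusters 1 and 3 together the shares were 42.5% of 280 control (36.6 to 48.5) and 30.2% of 2231 knockdown cells (28.3 to 32.1). This gap was smaller than that over all cells. In cluster 1 alone they were 2.19% of 137 control and 2.02% of 1439 knockdown cells and in cluster 3 alone 81.1% of 143 and 81.3% of 792. The clusters themselves part by phase, so the shares within each cluster alone do not bear on the pooled gap. Within cluster 1 the S phase median was -0.13 and the G2 and M phase median -0.22, and within cluster 3 they were -0.29 and 0.09. The same limit holds for these medians.

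**Figure D4:**
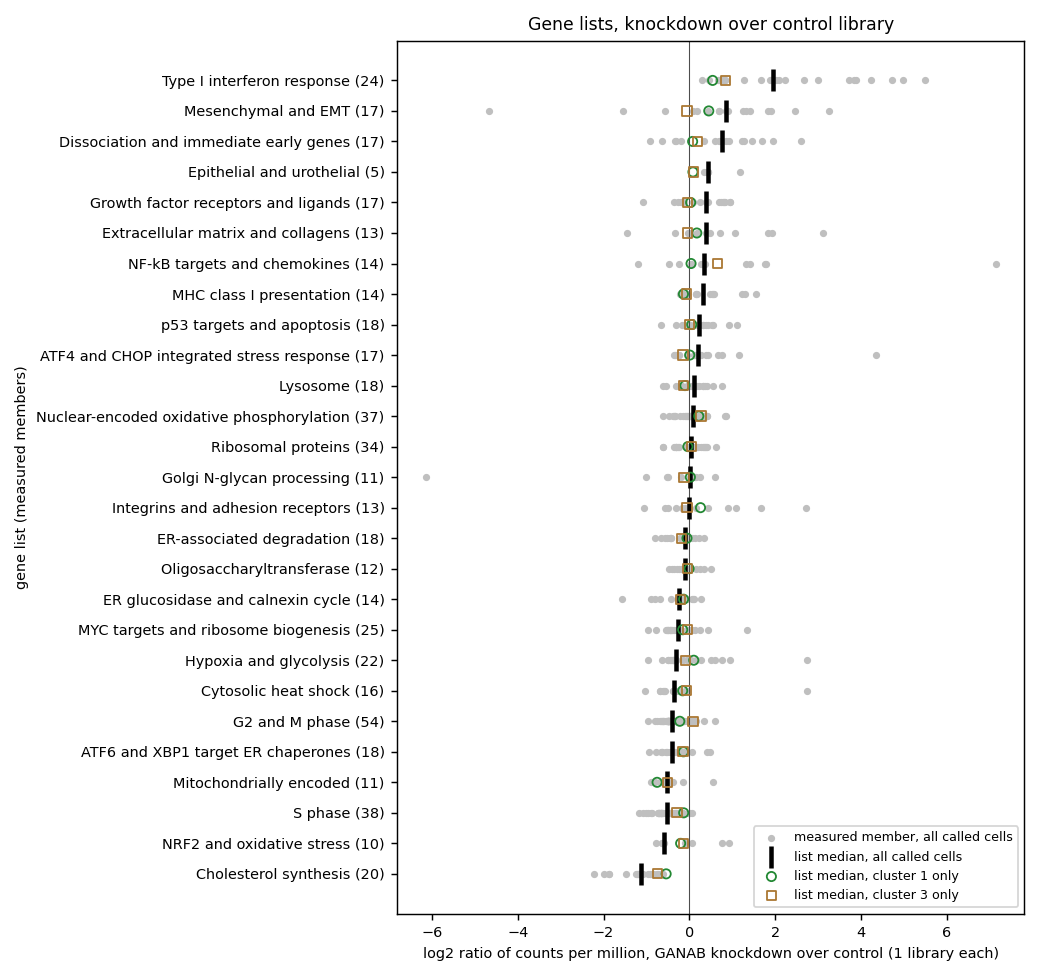
Log2 ratios of CPM, knockdown over control, for the measured members of 27 gene lists (grey points), with the list median over all called cells (black bar) and within clusters 1 (circle) and 3 (square). The interferon median lies at 1.96 over all cells and at 0.54 and 0.84 within the clusters, and the cholesterol median at -1.12, -0.54 and -0.75.

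Mesenchymal genes were higher as a group in the whole library, but not in cells of cluster 3. Of 17 measured members 11 were higher and 2 lower, with a median of 0.86 at percentile 100, which was 0.44 at a minimum of 50 CPM. VIM, the intermediate filament of mesenchymal cells, was at 3541 CPM in control and 5708 in knockdown cells, S100A4 at 5.82 and 32.1, and TAGLN at 1.68 and 16.0. The hyaluronan receptor CD44 (235 and 159) was not past the size rule. The member CDH2 went the other way, at 42.0 in control cells outside clusters 1 and 3. It was at 2.67 in the control cells and 1.09 in the knockdown cells of those clusters. Within clusters 1 and 3 VIM stood at 3587 against 5566 and 4621 against 6015, and TAGLN at 18.8 against 17.4 and 13.6 against 15.5. The list median there was 0.45, with 6 higher and 2 lower, and -0.06, with 3 higher and 3 lower. Extracellular matrix genes had 5 of 13 higher and 1 lower (median 0.38, percentile 99.8; 0.19 with cells called at a minimum of 5000 UMIs). COL5A1 was at 1.82 and 15.7, COL4A2 at 3.99 and 15.3, SPARC at 59.8 and 213, and PLOD2, a collagen lysyl hydroxylase, at 122 and 44.5. Their median was 0.17 within cluster 1 and -0.05 within cluster 3, where SPARC had log2 ratios of 0.71 and -0.16 and PLOD2 of -0.22 and -0.49. Integrins and adhesion receptors had 4 of 13 higher and 1 lower, ITGB5 (58.5 and 28.2), around a median of -0.02, which was 0.26 and -0.06 within the clusters. Growth factor receptors and ligands had 7 of 17 higher and 1 lower (median 0.40, percentile 100), with AXL, a receptor kinase, at 67.4 and 109, TGFBR2 at 25.2 and 48.2 and FGF2 at 14.6 and 28.2. At a minimum of 50 CPM the median was -0.14. Within the clusters AXL stood at 54.0 against 74.5 and 113 against 149, which did not pass the size rule, TGFBR2 was at 80.4 against 66.6 and 40.9 against 27.6, and the medians were 0.03 and -0.04. Only 5 epithelial and urothelial genes were measured, with a median of 0.42, KRT7 at 8.12 and 18.4 and KRT18 at 202 and 273; within clusters 1 and 3 the medians were 0.08 and 0.09.

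Metabolic lists pointed in several directions. Mitochondrially encoded genes had 4 of 11 lower and none higher (median -0.52, percentile 0.06), with MT-CYB at 2654 CPM in control and 1425 in knockdown cells and MT-CO3 at 2425 and 1386. Without the cells poor in both MALAT1 and mitochondrial UMIs, which were more common in the knockdown library, the median was -0.41. The difference was present within cluster 1 (median -0.75, with 8 lower) and cluster 3 (-0.51, with 5 lower). Cluster 8, low in MALAT1 and mitochondrial UMIs (median 0.018%), held 272 control but only 6 knockdown cells. The 474 knockdown cells poor in both thus lay mostly in other clusters. Poor cells may therefore weigh unequally within clusters 1 and 3, where they were not left out. Nuclear genes of oxidative phosphorylation had 2 of 37 higher, NDUFA13 (227 and 408) and ATP5ME (245 and 434), and 1 lower, ATP5PB, around a median of 0.07; within the clusters it was 0.22 and 0.27. Hypoxia and glycolysis genes had 2 of 22 lower and 4 higher around a median of -0.31 (percentile 0.77). LDHA was at 451 and 229 and ENO1 at 1232 and 794, while within the clusters the medians were 0.10 and -0.09 and the log2 ratios were -0.33 and -0.07 for LDHA and -0.58 and -0.11 for ENO1. The NRF2 list had 5 of 10 lower and 2 higher, with a median of -0.60 at percentile 0.00. This median was -0.11 at a minimum of 50 CPM, -0.15 with no minimum and -0.34 with totals lacking mitochondrial and ribosomal genes. GCLM of glutathione synthesis was at 74.2 and 43.4 and PRDX1 at 1017 and 648, but TXN was at 1397 and 2357 and the ferritin light chain FTL at 1523 and 2902. Its medians within clusters 1 and 3 were -0.21 and -0.14. Ribosomal proteins (1 of 34 higher, RPL34, and 2 lower) had a median of 0.05. MYC targets and ribosome biogenesis genes (2 of 25 lower, among them ODC1 at 233 and 137, and 1 higher, CCND2) had a median of -0.27, and of -0.16 and -0.05 within the clusters.

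Stress and early response genes completed the lists. Immediate early genes, which tissue dissociation also induces, had 11 of 17 higher and 2 lower (median 0.75, percentile 100), with KLF4 at 7.46 CPM in control and 45.5 in knockdown cells, NR4A1 at 41.9 and 162 and DUSP1 at 480 and 1121, whereas JUN was at 834 and 658. Within clusters 1 and 3 the medians were 0.07 and 0.20, with DUSP1 at 1351 against 1335 and 780 against 894 and NR4A1 at log2 ratios of 0.07 and 0.25. Cytosolic heat shock genes had 4 of 16 lower and 1 higher (median -0.36, percentile 0.39), among them HSPA1A (1264 and 621) and DNAJA1 (491 and 303), and medians of -0.16 and -0.07 within the clusters. The p53 and apoptosis list had 2 of 18 higher, GADD45B (55.6 and 121) and BBC3 (10.0 and 18.9), and 1 lower around a median of 0.23, against 0.05 within cluster 1 and near 0 within cluster 3. The share of cells poor in both MALAT1, a nuclear RNA, and mitochondrial UMIs, a sign of damaged or stripped cells, was 10.8% in the control (9.91 to 11.8) and 18.0% in the knockdown library (16.6 to 19.5).

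Markers of other cell types were summed over called cells after leaving out those at 10 CPM or more in either library. This choice itself keeps the sums low, so they do not measure how rare such cells were. Among the markers kept, those of fibroblasts reached 15.8 CPM in the control and 14.0 in the knockdown library. Macrophage or monocyte markers reached 2.72 and 4.42, smooth muscle or pericyte markers 2.48 and 4.50, and differentiated urothelium markers 2.21 and 2.25. Neutrophil (0.794 and 1.43), B cell (0.334 and 1.03), erythroid (1.26 and 0.661), endothelial (0.321 and 0.653), T or NK cell (0.0511 and 0.0380) and mast cell markers (0.0279 and 0.152) were lower still. The UMUC3 list of cytoskeletal and adhesion genes, from which no marker was left out, summed to 13943 CPM in control and 17044 in knockdown cells. In barcodes of 1 to 10 UMIs it summed to 14545 and 16544, so it does not set called cells apart. Cluster 10, led by the collagens COL1A1, COL1A2 and COL3A1 and the keratin KRT14, held 50 control and 19 knockdown cells, 1.12% (0.833 to 1.47) and 0.722% (0.435 to 1.13) of each library.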

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

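Of the tests in this part, that of free RNA was chosen after the result was seen, as was the choice of single blood genes. Marker genes of other cell types were counted in barcodes that were not called as cells, in 2 ranges, and in 10 instances lay above the control library in the knockdown library with Poisson 95% intervals that did not overlap. In barcodes of 1 to 10 UMIs, neutrophil markers were at 262 CPM in the knockdown and 1.1 in the control library, and erythroid markers at 257 and 1.1. Fibroblast markers were at 364 and 214 there, smooth muscle or pericyte markers at 76.7 and 29.2, macrophage or monocyte markers at 65.9 and 33.1, B cell markers at 43.5 and 6.61, and differentiated urothelium markers at 8.3 and 2.48. In barcodes from 1000 UMIs up to the calling cutoff, smooth muscle or pericyte markers were at 404 and 128, differentiated urothelium markers at 25 and 17.6, and neutrophil markers at 2.98 and 0.509. By the same rule the control library was higher in this range for fibroblast (2084 in the knockdown and 2549 in the control library), macrophage or monocyte (20.7 and 36.3) and endothelial markers (5.22 and 10.5).

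Human haemoglobin HBB gave 356 of the 2047120 UMIs in knockdown barcodes of 1 to 10 UMIs, 174 CPM, and 4875 of 5178146 in those of 20 to 200 UMIs, 941 CPM, but 1 UMI in the called knockdown cells. The control library had 0 in both ranges, which allows up to 0.827 and 0.483 CPM. S100A8 had 314, S100A9 215, S100A12 113, CAMP 57 and DEFA3 18 UMIs in knockdown barcodes of 1 to 10 UMIs, where the control library had 0, 4, 0, 1 and 0. No explanation of these values was tested.

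Clustering of the cells called at a minimum of 1000 UMIs gave a group of 744 led by stromal genes such as SFRP2 and CXCL14, 313 from the control and 431 from the knockdown library, with a median of 1869.5 UMIs. It was chosen as the group with the highest level of fibroblast markers. These summed to 26540 CPM, 99.06 times their level of 268 in barcodes of 1 to 10 UMIs. Since the choice rested on the same markers, this ratio cannot decide against free RNA in empty droplets as the source. Markers of the UMUC3 list summed to 16524 CPM there and 15120 in called cells. Cells of the mouse host counted against human genes may account for the group. That explanation stays open. No biological explanation was tested, since the labels name no other cell type.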

How the results depend on the processing

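The values within clusters 1 and 3, without cluster 9 or 10, without cells poor in MALAT1 and mitochondrial UMIs, and against control cells outside clusters 1 and 3 come from choices made after seeing the data, and the other settings were fixed in advance. Under the 13 settings fixed in advance GANAB lay between -1.62 and -1.55. Each list median was counted once per setting fixed in advance. Of these, 27 come from the setting of all called cells, identical to the values given. In all, 396 stayed within their spread and 8 moved. Those spreads are wide, and at 50 or more CPM the median of growth factor receptors and ligands went from 0.40 to -0.14 and that of Golgi processing from 0.01 to -0.25. The NF-kB median went from 0.33 to 1.33 at 50 or more CPM, 0.18 with equal weights, 0.19 with thinned cells and 0.12 in G1 cells, the MHC class I median from 0.32 to 0.53 at 50 or more CPM and 0.16 with no minimum, the ATF4 and CHOP median from 0.19 to 0.38 and the hypoxia median from -0.31 to -0.06 with no minimum, and the matrix median from 0.38 to 0.25 with TMM factors. The epithelial median went from 0.42 to 0.68 with no minimum, that of MYC targets from -0.27 to -0.41 with thinned cells, that of oligosaccharyltransferase from -0.11 to -0.22 at 50 or more CPM and -0.06 in G1 cells, and that of lysosome from 0.11 to 0.05 at 50 or more CPM and 0.19 with equal weights. Medians nearer 0, of ER-associated degradation, integrins, oxidative phosphorylation and ribosomal proteins, also moved by more than 1.5 times. With each named gene counted once per setting, 448 stayed and 284 moved, and none past the size rule changed direction. Of the 448, 122 come from that identical setting. TMM and median-of-ratios factors shifted the median of all genes by -0.03 and -0.04. No paired analysis was possible with 1 library per group. No cause was tested for any change below. Intervals within clusters rest on fewer counts, with 5594029 control UMIs in cluster 1 and 9362352 in cluster 3.

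Within cluster 1, GANAB was at -1.66 and the medians were -0.13 for S phase (-0.52 over all cells), -0.22 for G2 and M phase (-0.41), 0.54 for interferon (1.96) and -0.54 for cholesterol synthesis (-1.12). Medians that changed side were those of lysosome (-0.10), integrins (0.26), MHC class I (-0.14), hypoxia (0.10) and ribosomal proteins (-0.04). Genes past the size rule over all cells that changed side there were VGF (0.0083), BDKRB1 (1.29), SEMA3A (-0.22), FAM133A (-0.15), PHGDH (-0.071), TAGLN (-0.12), TGFBR2 (-0.27), FGF2 (-0.070), PCNA (0.078), KIF2C (0.093), IFITM3 (-0.70), HLA-F (-0.0018), PRDX1 (0.084) and DUSP1 (-0.017). Within cluster 3, GANAB was at -1.63, S phase at -0.29, cholesterol synthesis at -0.75, and medians that changed side were those of mesenchymal genes (-0.058, from 0.86), G2 and M phase (0.085), ATF4 and CHOP (-0.15), Golgi processing (-0.13), lysosome (-0.13), matrix (-0.05), growth factors (-0.04), MHC class I (-0.07) and p53 (-0.0048). Among genes past the rule, so did VGF (0.065), C15orf48 (0.97), BDKRB1 (2.24), TMEM132D-AS1 (-0.21), SEMA3A (-0.65), FAM133A (-0.056), PHGDH (-0.44), NUPR1 (-0.24), SPARC (-0.16), TGFBR2 (-0.57), FGF2 (-0.0385), CDC20 (0.17), KIF2C (0.13) and IFITM3 (-0.012).

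With cells weighted equally the S phase and G2 and M phase medians were -0.73 and -0.59, with thinned cells -0.74 and -0.54, and in G1 cells -0.24 and -0.18. Members called lower numbered, for G2 and M phase, 9 over all cells, 28 with equal weights, 24 thinned, 4 in G1 cells, 4 at 50 or more CPM and 0 in cluster 3. S phase had 17, then 3 in G1 cells, 7 at 50 or more CPM and 2 in each cluster. ER chaperones had 5, then 2 in G1 cells, 1 in cluster 1 and 0 in cluster 3. The calnexin cycle had 4, then 2 in each cluster. Cholesterol synthesis had 20, then 11 at 50 or more CPM, 9 in cluster 1 and 12 in cluster 3. Interferon had 22 higher, then 12, 11 and 14 there. At 50 or more CPM fewer members were measured, with unchanged ratios.

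A minimum of 1000 UMIs per barcode gave median UMIs of 26796.5 in control and 11703 in knockdown cells (43600.5 and 41293 as given), 4.27% and 8.10% of cells in clusters led by markers of another type (1.12% and 0.722%), 11.9% and 77.1% in clusters mostly of knockdown cells (6.90% and 98.1%), and 32.5% of knockdown cells in S or G2M (29.3%). A minimum of 5000 UMIs gave median UMIs per control called cell of 40441 and median UMIs per knockdown called cell of 33672.5, 93.3% of knockdown cells in clusters mostly of knockdown cells, and 48.8% of control cells in S or G2M (50.9%). Without doublet removal the phase shares were 53.1% and 31.2%. At resolution 0.25, clusters led by another type held 0.695% and 0.190%, and 98.6% of knockdown cells were in clusters mostly of knockdown cells. With principal components centred within each library, 1.37% of knockdown cells were in clusters led by another type, and 1.48% of control and 89.9% of knockdown cells in clusters mostly of knockdown cells.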

Other observations

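Of the tests in this part, those of mixed-in knockdown cells, of a subclone and of a lost knockdown were chosen after the result was seen, as were the choice of genes by the smaller of their ratios within clusters 1 and 3 and the marker sums of cluster 9. Among the 2147 genes compared that way, all with at least 50 CPM in the higher library within each cluster, GANAB had the lowest ratio. MAN1A1 and MME fell under that limit and had lower ratios in both clusters. GANAB was followed by NNMT, a nicotinamide methyltransferase, at 495 CPM in control and 183 in knockdown cells of cluster 1 and at 219 and 91.1 in cluster 3. CALD1, which binds actin and tropomyosin, was at 186 and 87.0 and at 301 and 115, the Notch target HES1 at 296 and 81.9 and at 123 and 61.3, and the chromatin protein HMGA1 at 198 and 113 and at 877 and 509.5. The sterol genes MSMO1 and HMGCS1 and the fatty acid desaturase FADS1 (69.4 and 36.6; 149.5 and 70.7) were also among the 12 lowest.

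The 12 highest by the same rule and limit began with CCL5, and held 3 neutrophil chemoattractants, CXCL1 (20.2 and 102; 41.1 and 116), CXCL3 (52.2 and 121; 62.4 and 169) and CXCL2. IFIT1, IFIT2, BST2 and IFI27 fell under the limit in cluster 3, and the smaller of their ratios exceeded that of CCL5. S100A10, a partner of annexin A2, was at 1459 and 3634 in cluster 1 and at 1217 and 2454 in cluster 3, and the caveolar protein CAV1 at 752 and 1467 and at 498 and 788. TGM2, a transglutaminase, and EMB were lower in the knockdown cells of both clusters (TGM2, 162 and 99.2; 185 and 104), although their log2 ratios over all called cells were 0.98 and 0.15.

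The 303 control cells that grouped with knockdown cells are the pattern that most affects the comparison. Their GANAB level was 1.059 times that of other control cells (1.01 to 1.11), which argues against knockdown cells mixed into the control library. A barcode also called in the knockdown library was carried by 0% of them, which argues against barcode swapping. The limit of that share was 0.990% by 3 counts and 1.21% by Clopper-Pearson. Windowed log2 ratios along the autosomes correlated at 0.912 with those of the knockdown cells. With gene positions shuffled the correlation was 0.628 on average and at most 0.742, so much of it does not depend on gene order. Random draws of other control cells gave at most 0.221. The 303 cells were grouped by likeness to knockdown cells and the draws were not, so the draws decide nothing. The excess over shuffled positions is compatible with a subclone of the line, rare in the control and common in the knockdown library. Expression along chromosomes is not a count of DNA copies, and control cluster 4 also had windows 3.34 times as variable as shuffled ones, with a correlation of -0.06. Under this hypothesis part of the difference between the libraries may come from clone composition, and an effect of the knockdown on which cells grew stays open and untested.

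The 104 interferon-high knockdown cells of cluster 9 had GANAB at 1.07 times the level of other knockdown cells (0.913 to 1.25), which argues against a lost knockdown. Without them the interferon median was 1.716, so the list difference does not rest on them alone. The leukocyte gene PTPRC had 0 UMIs, with an upper limit of 0.9874 CPM, below the 10 expected beforehand of immune cells. The bound of 3 times the level in other knockdown cells was set beforehand for sums of all listed markers but CCL5. By these sums, macrophage or monocyte markers were at 1.70 times (1.54 to 1.87) and neutrophil markers at 1.03 times (0.959 to 1.10) that level. Sums without the markers at 10 CPM or more in either library, a later choice, were at 4.84 times (3.72 to 6.20) and 85.6 times (62.0 to 120). The neutrophil sum after that choice was 36.1 CPM, and S100A9 gave 125 of its 135 UMIs, from 6 of the 104 cells. The macrophage sum after that choice, 72 UMIs, came from CTSS (52), CD74 (19) and CSF1R (1), with 0 for LYZ, CD14 and TYROBP. T and NK cell markers without CCL5 had 1 UMI, at 8.56 times (0.174 to 86.5). B cell markers had 1 UMI, at 0.254 times (0.0064 to 1.44). Immune cells of the host, or doublets with them, stay open, since these values part and mouse transcripts could be undercounted. A response of tumour cells to the knockdown, to the vector that carried it or to their place in the bladder stays open and untested.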
